A study of Mus musculus with 9 samples.

How the data were processed

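RNA levels were measured in jejunum of control mice, jejunum of Gata4 mutant mice and ileum of control mice. Each group had 3 mice and 3 arrays, with 9 arrays in all. All mice carried villin-Cre and 1 loxP-flanked copy of Gata4, beside a null copy in mutants and a wild-type copy in controls. Per the labels' protocols, total RNA was purified on RNeasy columns, amplified with the Affymetrix one-cycle procedure and labelled with biotin. Per the submitters' processing notes, the deposited intensity values were made with GCOS, the Affymetrix scanner and expression software; its version and settings are not given in the sources used here. The table deposited by the authors holds 1 intensity per probe set and array on a linear scale, summarised over the probes of each probe set. The groups come from the sample titles. The design text gives separate mice for each group, so the replicate error includes the spread between animals. Age (6 to 8 weeks), sex and the distances along the gut come from that text as well, and scan dates and array batches are not given in the sources used here.

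The comparisons, tests, gene lists, rule for named genes and alternative settings were fixed before the data were examined. The planned main values were log2(intensity + 16) with no scaling between arrays, on the premise that GCOS had scaled each array to a common target. The values spoke against that premise: the mean intensity after trimming 2% at each end ran from 96.8 to 180 over the 9 arrays, a ratio of 1.86, and stood at 0.673 in ileum relative to jejunum arrays. Hybridization spike controls, which are added in equal amounts, stood at 0.572 in ileum relative to jejunum arrays. Quantile normalization of log2(intensity + 16), which was among the alternatives fixed in advance, was therefore taken as the main setting before any calls were compared, and the unscaled values became an alternative. Quantile normalization gives every array the same distribution, so a change of all transcripts in one direction could not be seen. Fold changes are differences on this log2 scale, which understates the change of dim probe sets.

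Of 45101 probe sets, 64 array controls were left out before normalization, and no column of values was left unmapped. A probe set was tested if at least 3 of the 9 arrays exceeded the 40th percentile of all values (4.95 on the log2 scale), a filter blind to group that kept 29307. Gene names come from the annotation table given for the array's probe sets, where 34945 probe sets have 1 gene, 932 have several and 9160 have none, so that some probe sets are unnamed here. The table's Entrez identifiers matched the RefSeq gene table of the GRCm38.p6 assembly for 34741 probe sets, and no symbol changed. That table was also used for the order of genes along chromosomes. No gene was named from a probe set with several, and the tested probe sets cover 13830 genes. Where a gene had several tested probe sets, the one with the highest mean over the 9 arrays stood for it, and the text says where the others were not called alike.

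Differences were tested in limma 3.58.1 under R 4.3.3, with lmFit over all 9 arrays, 3 contrasts from 1 fit, eBayes with an intensity trend and two-sided tests. P-values were adjusted over all probe sets tested in a contrast by the Benjamini-Hochberg method, and a call is an adjusted p under 0.05. All adjusted p-values of single genes come from this limma model, in which the 3 groups share 1 estimate of the spread. An exact permutation test of 3 against 3 arrays cannot go below p = 0.10 and was not used for single genes. Regional probe sets were those called between control ileum and control jejunum with at least a 2-fold difference. The position of the mutant on each was the mutant array minus the control jejunum mean, divided by the control ileum mean minus the control jejunum mean, and the median over probe sets was taken per mutant array. Levels outside both control segments were those called with the same sign against control jejunum and against control ileum. Because the mutant and regional contrasts share their control jejunum arrays, 100 data sets were simulated. In these, mutant arrays were drawn around the control jejunum means and ileum arrays around their own, with normal noise at the fitted spread. The noise was drawn for each probe set alone, so shifts shared by many probe sets of an array were left out.

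The text names, for each contrast, the 10 genes with the largest rise and the 10 with the largest fall among calls in which the 3 arrays of one group lay beyond the 3 of the other. It also names the 5 genes furthest above and the 5 furthest below both control segments, Gata4, and members of the gene lists as examples. The 33 gene lists were fat absorption, sterol transport, sterol synthesis, bile acid handling, distal small intestine, proximal mineral and vitamin uptake, brush border hydrolases, transport of sugars, amino acids and peptides, xenobiotic metabolism, fatty acid oxidation, regional transcription factors, purine breakdown, enteroendocrine, Paneth, goblet, tuft, crypt stem, cell cycle, epithelial identity, antigen presentation, interferon response, epithelial defence, circadian, stress and handling, B and plasma cells, T cells, myeloid cells, smooth muscle, enteric neurons and glia, stroma and vessels, pancreatic acinar, mesenteric fat and blood, and a sex check. Of their 509 entries, 441 were measured. Lists were tested with camera in limma on 1 probe set per gene, with a preset correlation between genes of 0.01, adjusted over the 33 lists of a contrast, and again with the correlation estimated from the data. Counts of list members are also given adjusted over the list alone.

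The alternatives were no scaling between arrays, arrays centred on their medians, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, no intensity trend, array weights, a fit of the 2 groups compared, the replicate number as a block, 1 probe set per gene, an adjusted p under 0.01, other fold minimums for regional genes and leaving out each array in turn. For the gene lists, a further alternative let the probe set of smallest p stand for each gene. Scaling to the trimmed mean was added after seeing the data. Where leaving out an array leaves 2 in a group, the pooled spread of the fit is used. The fitting steps were tested on simulated data made from the control jejunum means: of 50 probe sets changed at each size, 2 were called at a log2 change of 0.5, 27 at 1, 50 at 2 and 49 at 3, and 11 of 139 calls were false in the simulated comparison of mutant with control jejunum. No arrays held identical values. Actin 3' to 5' probe ratios ran from 1.19 to 1.40 and those of Gapdh from 0.694 to 0.814.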

Results

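Total RNA from the small intestine of adult male mice, 6 to 8 weeks old, was hybridized to Affymetrix mouse expression arrays, 1 array per mouse. Control jejunum (n = 3) and control ileum (n = 3) came from independent mice that carried 1 loxP-flanked and 1 wild-type copy of Gata4, a zinc finger transcription factor of the proximal gut. Mutant jejunum (n = 3) came from mice with 1 loxP-flanked and 1 null copy. All mice carried a villin-Cre transgene, which expresses Cre recombinase in the intestinal epithelium. The loxP-flanked copy was thus exposed to Cre in controls as well, and the groups differed in the other copy. Jejunal samples lay 10 cm beyond the pylorus and ileal samples 1 cm before the cecum, and the layers of the gut wall in each sample are not given in the sources used here. Trimmed mean intensity was 163 ± 12.0 on the control jejunum arrays, 169 ± 18.2 on the mutant jejunum arrays and 112 ± 13.2 on the control ileum arrays (SD, n = 3 each), so the ileum arrays were dimmer as a group. Brightness and segment cannot be told apart. Of the mutant arrays, mutant jejunum 3 lay apart on the second principal component (-55.8, against 12.0 and 7.06 for the other two) and took the lowest array weight, 0.384. Levels are normalized log2(intensity + 16), on which an intensity near 0 gives about 4, and are given as mean ± SD with n = 3 per group. With 3 arrays per group, the number of arrays limits the precision of each value.

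Gata4, the targeted gene, was measured by 2 probe sets. The brighter one stood at 9.57, 9.49 and 9.52 in control jejunum 1, 2 and 3, at 9.61, 9.51 and 9.38 in mutant jejunum 1, 2 and 3, and at 5.64, 5.30 and 5.20 in control ileum 1, 2 and 3. The dimmer one stood at 8.07, 7.30 and 7.34, at 8.47, 8.29 and 7.91 and at 4.90, 4.59 and 4.26 in the same order. Neither probe set of Gata4 was called between mutant and control jejunum (log2 difference -0.02, adjusted p = 0.959, and 0.65, adjusted p = 0.195), though the dimmer one was higher in the mutant with array weights (log2 difference 0.78, adjusted p = 0.0467). Both were lower in control ileum than in control jejunum, with log2 differences of -4.15 and -2.99. Where these probe sets lie relative to the deleted part of Gata4 is not given in the sources used here, so their levels check nothing about the deletion.

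The comparison of mutant with control jejunum shows which transcripts differed between the jejunum of mice with 1 loxP-flanked and 1 null copy of Gata4 and that of controls. Genes of ileal bile acid uptake and signalling rose in mutant jejunum from near background to levels close to or above those of control ileum. Fabp6, the bile acid binding protein of ileal enterocytes, stood at 4.84 ± 0.19 in control jejunum, 13.90 ± 0.00 in mutant jejunum and 13.74 ± 0.10 in control ileum. It rose by 9.06 on the log2 scale (adjusted p = 3.57e-12). Slc10a2, the apical sodium-dependent bile acid transporter, rose by 5.74 to 10.08 ± 0.56 (adjusted p = 8.75e-07), against 10.71 ± 0.31 in control ileum. Fgf15, the hormone that ileal enterocytes release in response to bile acids, rose by 4.17 to 8.30 ± 1.24 (adjusted p = 0.00269), against 5.61 ± 1.02 in control ileum. The other 7 of the 10 largest rises were Mgat4c, an N-acetylglucosaminyltransferase (4.59), Tmigd1 (4.21), the sulfite oxidase gene Suox (3.95), and the Paneth cell defensin Defa31 (3.77), followed by the mitochondrial carrier Slc25a48 (3.58, called in 1 of its 3 probe sets), the goblet cell product Retnlb (3.36) and the phosphate transporter Slc34a2 (3.30). Fabp6, Slc10a2, Fgf15, Slc25a48 and Retnlb rose from levels near background, so the size and order of these rises depend on the pseudocount (10.16, 7.99, 6.88, 6.22 and 5.99 with 1, and 7.64, 4.05, 2.51, 2.01 and 1.82 with 64, where Mgat4c gave 5.10 and 3.69). The mutant level of Fabp6 is also the top of the normalized scale. The alpha-defensins are near-identical copies, so the Defa31 signal may hold several of them. The call of Retnlb (adjusted p = 0.0318) was lost without control jejunum 1, 2 or 3 (adjusted p = 0.0692, 0.116 and 0.115) or mutant jejunum 1, 2 or 3 (adjusted p = 0.0626, 0.114 and 0.0707) or with a pseudocount of 64 or no filter (adjusted p = 0.195 and 0.0545). Quantile normalization gives equal ranks equal values, which is why the SD of Fabp6 is 0 in the mutant group.

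The 10 largest falls in the mutant included single genes of digestion, nutrient uptake and drug metabolism, and the lists they belong to are given below with their tests. Lct, the lactase of the brush border, went from 12.96 ± 0.21 in control to 8.85 ± 1.45 in mutant jejunum, where control ileum stood at 4.80 ± 0.33. It fell by 4.11 (adjusted p = 0.00180). The largest fall was that of the cytochrome P450 gene Cyp2b10, from 12.17 ± 0.35 to 6.33 ± 1.43, close to its 5.23 ± 1.10 in control ileum. It fell by 5.84 (adjusted p = 0.000554). Reg1, a secreted lectin, fell by 4.62, Dnase1, a secreted deoxyribonuclease, fell by 4.20, and Slc46a1, the proton-coupled folate transporter, fell by 3.87. Cd36, the fatty acid translocase, fell by 3.66 from 10.39 ± 0.22 to 6.73 ± 0.39 (adjusted p = 0.00284), with control ileum at 6.32 ± 1.36. The remaining members of the 10 largest falls were Bbox1, an enzyme of carnitine synthesis (-3.41), Hsd17b6 (-3.39), the monocarboxylate transporter Slc5a12 (-3.37) and the P450 gene Cyp2c29 (-3.36). The call of Cyp2c29 (adjusted p = 0.0324) was lost without control jejunum 1, 2 or 3 (adjusted p = 0.0793, 0.0665 and 0.132), mutant jejunum 2 or 3 (adjusted p = 0.120 and 0.0713) or control ileum 2 (adjusted p = 0.0508) or with a pseudocount of 1, no filter, no intensity trend or a fit of the 2 groups alone (adjusted p = 0.0514, 0.0548, 0.0502 and 0.0688).

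Among 29307 probe sets tested, 511 rose and 533 fell in mutant against control jejunum at adjusted p under 0.05 (limma). Of these, 199 and 259 changed at least 2-fold, and the calls named 380 and 389 genes. The rises made up 48.9% of the calls, and 62.0% with arrays centred on their medians (523 rose and 320 fell). The groups did not overlap for 6582 probe sets (22.5%), where chance gives 10%. Without control jejunum 2 the counts were 214 and 204, without control jejunum 3 they were 207 and 193, without mutant jejunum 2 they were 210 and 222, and without mutant jejunum 1 the rises numbered 337.

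**Figure D1:**
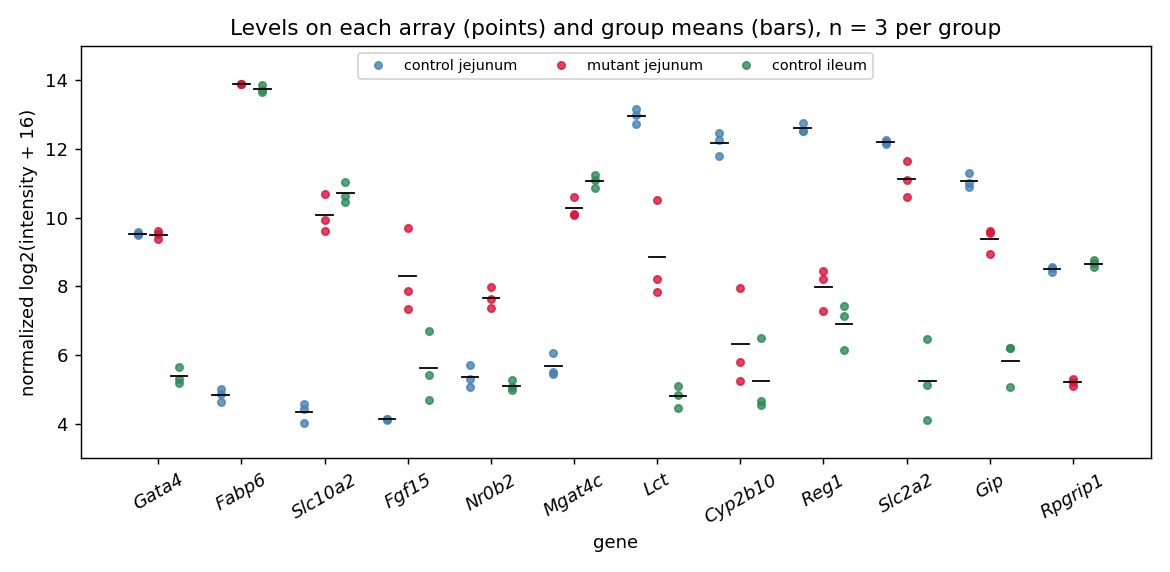
Normalized log2(intensity + 16) of 12 genes on each array (points; control jejunum, mutant jejunum and control ileum, n = 3 each) with group means (bars). Fabp6 and Slc10a2 in mutant jejunum lie near control ileum, Lct lies between the segments, Rpgrip1 lies below both, and Gata4 stays at 9.50 ± 0.11 in mutant jejunum.

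Of the 10 measured genes of bile acid handling, 7 rose, 1 fell and 2 were not called (adjusted over the list alone, 7 rose and 1 fell). Besides Fabp6, Slc10a2 and Fgf15, the rises were those of Slc51a (1.55) and Slc51b (2.34), which form the basolateral bile acid exporter, Nr1h4 (1.70), the bile acid receptor, and Nr0b2 (2.32), a repressor that this receptor induces. Cyp27a1, an oxidase of bile acid synthesis, fell by 1.63. The list's median change was 2.01 (camera adjusted p = 3.12e-11, or adjusted p = 0.0166 with an estimated correlation). Of the 16 markers of the distal small intestine, 5 of which are also in the bile acid list, 8 rose and none fell (8 and 1 adjusted over the list alone). The distal list's median was 1.02 (adjusted p = 3.12e-11, or adjusted p = 0.00888 with an estimated correlation). They included the hormones Pyy (1.46) and Nts (1.65) and Guca2a (1.47), the peptide guanylin, whereas the glucagon gene Gcg was not called (-0.30). These were the 2 lists of the 12 called in this comparison that kept their call with an estimated correlation.

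Among the 20 genes of fat absorption, 4 fell and 1 rose (11 and 1 adjusted over the list alone), and 15 were not called. Cd36 and Dgat2, an enzyme of triglyceride synthesis (-1.22), fell, and Agpat2, an enzyme earlier in that pathway, rose by 0.75, while the fatty acid binding proteins Fabp1 (-1.34, adjusted p = 0.397, called with a fit of the 2 groups alone (adjusted p = 0.0194)) and Fabp2 (-0.04) were not called. The list's median was -0.34 (adjusted p = 6.23e-05, or adjusted p = 0.466 with an estimated correlation). Cholesterol synthesis moved the other way: 5 of its 19 measured genes rose and none fell (12 and 0 adjusted over the list alone), among them Sqle, the squalene epoxidase (1.25), and Fdps, the farnesyl diphosphate synthase (1.13, lost without control jejunum 2 (adjusted p = 0.0771) or mutant jejunum 2 (adjusted p = 0.0919)). Its median was 0.56 (adjusted p = 2.87e-08, or adjusted p = 0.466 with an estimated correlation). The mean of this list stood at 0.546, 0.783 and 0.365 on mutant jejunum 1, 2 and 3. On control jejunum 1, 2 and 3 it stood at -0.146, -0.182 and 0.328, so control jejunum 3 lay close to mutant jejunum 3. Sterol transport was not called as a list (median -0.36, adjusted p = 0.444). Of its 11 genes, Mylip, which targets the LDL receptor for breakdown, rose by 1.10 (lost without control jejunum 2 or 3 (adjusted p = 0.0802 and 0.0723)). Adjusted over the list alone, 2 rose and 2 fell. Fatty acid oxidation was not called either (median -0.07, adjusted p = 0.710). In that list 2 of 18 genes rose, including the carnitine carrier Slc25a20 (0.86), and 1 fell, the same counts as adjusted over the list alone.

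Of 16 transporters of sugars, amino acids and peptides, 7 fell and 2 rose (12 and 3 adjusted over the list alone). The median of these transporters was -0.78 (adjusted p = 1.74e-06, or adjusted p = 0.312 with an estimated correlation). Slc7a8, an amino acid exchanger (-2.88), and Slc36a1, a proton-coupled amino acid transporter (-2.83), fell, and the glutamate transporter Slc1a1 rose by 1.52. Slc2a2, the basolateral glucose transporter, was at 11.12 ± 0.52 in mutant and 12.21 ± 0.05 in control jejunum and was not called (adjusted p = 0.264), though it was with a fit of the 2 groups alone (adjusted p = 0.0395). Of 18 brush border hydrolases, 4 fell and 2 rose (10 and 4 adjusted over the list alone). Besides Lct, the peptidase Ace fell by 2.50, while the meprin gene Mep1a rose by 2.02 and the peptidase gene Naaladl1 rose by 1.28. Their median was -0.35 (adjusted p = 0.0198, or adjusted p = 0.646 with an estimated correlation), and the call was lost without control jejunum 3 (adjusted p = 0.0579) or mutant jejunum 3 (adjusted p = 0.248) or with trimmed mean scaling, a filter at the 60th percentile or array weights (adjusted p = 0.101, 0.0621 and 0.0621). Xenobiotic metabolism had 4 falls and 1 rise among 24 genes (12 and 1 adjusted over the list alone). The median of the xenobiotic list was -0.75 (adjusted p = 1.86e-05, or adjusted p = 0.475 with an estimated correlation). Next to the P450 genes, the glucuronosyltransferase Ugt2b5 fell (-1.11) and the efflux pump Abcg2 rose (1.10), and several genes of this list belong to multigene families. Mineral and vitamin uptake was not called as a list (median -0.04, adjusted p = 0.775). Of 17 genes, 3 rose and 2 fell (5 and 4 adjusted over the list alone), with falls of Slc46a1 and of the vitamin C transporter Slc23a1 (-2.65). Purine breakdown was not called (adjusted p = 0.811). In all, 2 of 8 genes rose, among them the AMP deaminase gene Ampd3 (2.31-fold). Adjusted over the list alone, 2 rose and 2 fell. The purine median (-0.24) lay below 0 where its mean and test pointed up.

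Of 20 transcription factors of intestinal identity, 3 rose and 3 fell (4 and 4 adjusted over the list alone). Zfpm1, a cofactor of GATA proteins, fell by 1.40, while Osr2 rose by 1.68 and Foxa1 rose by 1.30; Onecut2 was not called (-0.43). Gata6, which encodes a related GATA factor, fell by 0.75 in 1 of its 3 probe sets (adjusted p = 0.0172), a call that was lost without control jejunum 2 or 3 (adjusted p = 0.0638 and 0.0765) or mutant jejunum 2 (adjusted p = 0.0835) or with no scaling between arrays or arrays centred on their medians (adjusted p = 0.0787 and 0.0713). The list was not called (adjusted p = 0.822), and its median (0.07) and test pointed up where its mean (-0.01) pointed down. Hormone genes of enteroendocrine cells moved both ways. Of 19, 3 rose, including Pyy and Nts, and 4 fell, including Cck, cholecystokinin (-1.93), and the incretin Gip (-1.69, lost without control jejunum 2 (adjusted p = 0.0552)), with 3 and 8 adjusted over the list alone. The enteroendocrine list was not called (median -0.27, adjusted p = 0.0843) and was called without mutant jejunum 3 (adjusted p = 0.0281) or control ileum 2 or 3 (adjusted p = 0.0280 and 0.0390) or with no scaling between arrays, arrays centred on their medians or array weights (adjusted p = 0.0407, 0.0309 and 0.0265). Goblet cell products rose as a list (median 0.32, adjusted p = 0.00268, or adjusted p = 0.312 with an estimated correlation). Of 13 goblet genes, 2 rose, including Retnlb, and none fell (5 and 0 adjusted over the list alone). General epithelial genes rose as well (median 0.18, adjusted p = 0.000228, or adjusted p = 0.312 with an estimated correlation). In this list 3 of 13 genes rose, among them the keratin Krt18 (0.84) and the tetraspanin Tspan8 (0.84, 2 of 5 probe sets), and none fell (5 and 0 adjusted over the list alone).

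No member of the Paneth, crypt stem or cell cycle lists was called in the mutant, and none of these lists was. Of 14 listed Paneth cell products 6 were measured, none of them an alpha-defensin, and Defa31, a defensin outside the list, rose by 3.77 (adjusted p = 0.000472). The median change was 0.20 over 6 Paneth cell products (adjusted p = 0.811; 1 fell adjusted over the list alone), -0.12 over 13 crypt stem cell markers (adjusted p = 0.710) and -0.06 over 19 cell cycle genes (adjusted p = 0.486, but called without mutant jejunum 3 (adjusted p = 0.00311)). Markers of cells outside the epithelium were not called between mutant and control jejunum, singly or as lists. The medians were -0.15 for smooth muscle (adjusted p = 0.139; called without control jejunum 1 (adjusted p = 0.00605) or mutant jejunum 2 (adjusted p = 0.000990)), -0.21 for enteric neurons and glia (adjusted p = 0.204; called with no scaling between arrays (adjusted p = 0.0474)), 0.09 for stroma and vessels (adjusted p = 0.444) and 0.15 for myeloid cells (adjusted p = 0.641). T cell markers had a median of 0.22 (adjusted p = 0.0778; called without control jejunum 1 (adjusted p = 0.0101) or control ileum 1 (adjusted p = 0.0366) or with no scaling between arrays (adjusted p = 0.0407); 1 rose adjusted over the list alone), and B and plasma cell markers a median of -0.19 (adjusted p = 0.375). Pancreatic acinar genes (0.26, adjusted p = 0.444), genes of mesenteric fat and blood (0.07, adjusted p = 0.728) and the sex check genes (0.06, adjusted p = 0.811) were not called either. For the lists of this paragraph other than the Paneth and T cell lists, no member was called adjusted over the list alone.

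**Figure D2:**
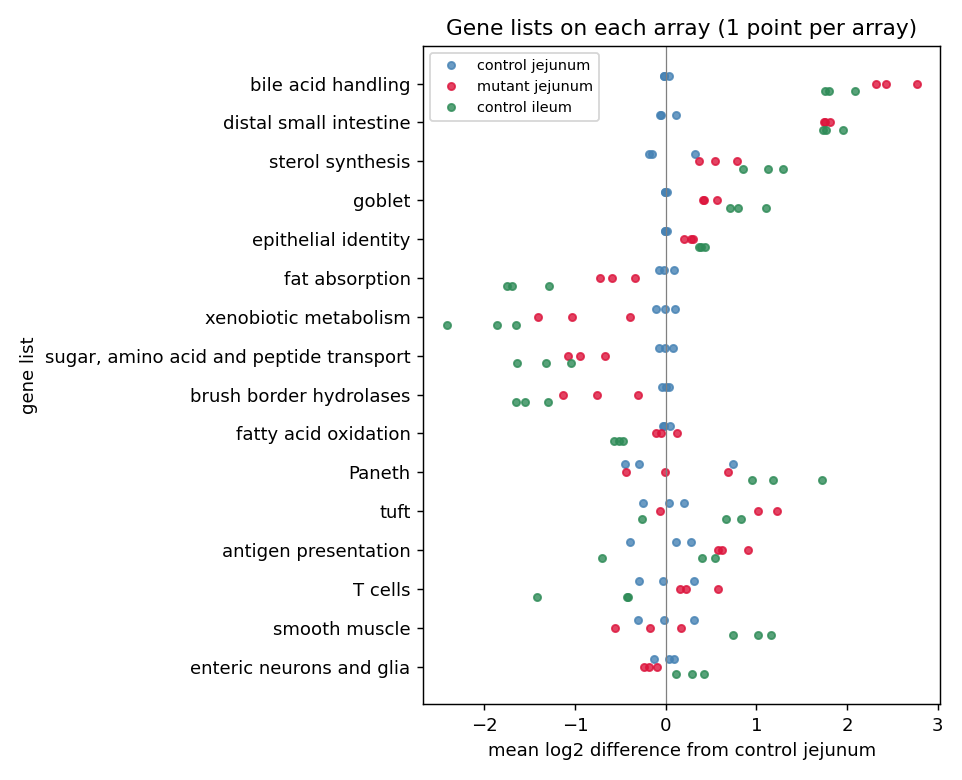
Mean log2 difference of each gene list from the control jejunum mean, 1 point per array (n = 3 per group). In mutant jejunum, the distal small intestine list lies with control ileum and the bile acid list above it, the fat absorption and xenobiotic lists lie between the segments, and the smooth muscle list of mutant jejunum lies with control jejunum.

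The comparison of control ileum with control jejunum gives the difference between the segments in control mice, which carry 1 loxP-flanked and 1 wild-type copy of Gata4 and the Cre transgene. Fabp6 (8.90) and Slc10a2 (6.37) were again among the largest rises in ileum, with Saa1, a serum amyloid A gene of epithelial defence (7.71), the amino acid transporter Slc6a14 (5.96), Mgat4c (5.39) and the phospholipase Pla2g4c (5.35). Saa1 stood at 4.18 ± 0.08 in control jejunum and 11.90 ± 1.13 in control ileum (adjusted p = 3.09e-05). Gsdmc2, a gasdermin (5.22), Retnlb (4.81), U90926 (4.74) and Slc25a48 (4.71) completed the 10 largest rises. Size and order again depend on the pseudocount for genes near background in control jejunum: with 1 and 64, Saa1 gave 10.28 and 5.87, Fabp6 10.00 and 7.48, and Slc25a48 7.43 and 2.96. The Pla2g4c call (adjusted p = 0.0152) was lost without control jejunum 2 or 3 (adjusted p = 0.0627 and 0.0622) or control ileum 1 or 2 (adjusted p = 0.0554 and 0.0573). Lct was lowest in ileum (-8.16), followed by Dnase1 (-7.09), Slc2a2 (-6.96), Cyp2b10 (-6.94), and the antimicrobial peptide Leap2 (-6.10). Cyp2c29 (-5.72), Reg1 (-5.70), the ectonucleotidase Enpp3 (-5.62, called in 4 of 5 probe sets), the glucuronosyltransferase Ugt2a3 (-5.60) and Fabp1 (-5.49) came next. Slc2a2 went from 12.21 ± 0.05 in control jejunum to 5.24 ± 1.19 in control ileum, and Fabp1 from 13.70 ± 0.00 to 8.21 ± 2.04, with an SD of 0 that again comes from equal ranks. The order of the falls also moved with the pseudocount, as Slc2a2 gave -8.29 and Dnase1 -8.10 with 1. In total, 2449 probe sets were higher and 2303 lower in control ileum (700 and 811 at least 2-fold, 1725 and 1530 genes). For 10952 probe sets (37.4%) the groups did not overlap, where chance gives 10%. Without control jejunum 2 the counts were 1486 and 1376, without control jejunum 3 they were 1495 and 1442, and without control ileum 2 the higher ones numbered 1520. The share higher in ileum was 51.5%, but 5.82% with no scaling between arrays (619 higher, 10013 lower, median shift of all probe sets -0.40) and 36.7% with arrays centred on their medians (1543 higher, 2665 lower). The split between higher and lower thus rests on the scaling of the dimmer ileum arrays.

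Genes of fat absorption, nutrient transport, digestion and drug metabolism were lower in control ileum. 15 of 20 fat absorption genes were lower in control ileum and none higher (15 and 1 adjusted over the list alone). The fat absorption list had a median of -1.02 (adjusted p = 1.41e-11, or adjusted p = 0.188 with an estimated correlation). These included Apoa4 (-3.50), an apolipoprotein of chylomicrons, and Mttp (-1.68), which loads them with lipid. 19 of 24 xenobiotic genes were lower in control ileum and 1 higher (20 and 2 adjusted over the list alone). The xenobiotic metabolism list had a median of -1.90 (adjusted p = 6.81e-11, or adjusted p = 0.192 with an estimated correlation). Examples were the P450 gene Cyp3a11 (-3.26) and the xenobiotic receptor Nr1i3 (-3.40). 11 of 16 transporters of sugars, amino acids and peptides were lower in control ileum and 2 higher (12 and 2 adjusted over the list alone). The sugar, amino acid and peptide transport list had a median of -1.12 (adjusted p = 3.42e-06, or adjusted p = 0.223 with an estimated correlation). 12 of 18 fatty acid oxidation genes were lower in control ileum and 1 higher (the same adjusted over the list alone). The fatty acid oxidation list had a median of -0.57 (adjusted p = 3.42e-06, or adjusted p = 0.188 with an estimated correlation). The fructose transporter Slc2a5 (-3.03) and the thiolase Acaa2 (-1.70) were among them. 10 of 18 brush border hydrolases were lower in control ileum and 4 higher (the same adjusted over the list alone). The brush border hydrolases list had a median of -0.97 (adjusted p = 0.0162, or adjusted p = 0.580 with an estimated correlation). This last call was lost with no scaling between arrays, trimmed mean scaling or a filter at the 60th percentile (adjusted p = 0.0896, 0.0605 and 0.0568). In it the trehalase Treh (-3.49) and the enteropeptidase Tmprss15 (-3.88) fell and Mep1a rose (2.63).

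Sterol synthesis, distal markers and bile acid handling were higher in control ileum. 13 of 19 sterol synthesis genes were higher in control ileum and none lower (15 and 0 adjusted over the list alone). The sterol synthesis list had a median of 1.32 (adjusted p = 9.25e-10, or adjusted p = 0.295 with an estimated correlation). 9 of 16 distal markers were higher in control ileum and none lower (11 and 0 adjusted over the list alone). The distal small intestine list had a median of 1.42 (adjusted p = 2.23e-09, or adjusted p = 0.0167 with an estimated correlation). 5 of 10 bile acid genes were higher in control ileum and 3 lower (6 and 3 adjusted over the list alone). The bile acid handling list had a median of 1.46 (adjusted p = 0.00210, or adjusted p = 0.188 with an estimated correlation). Sqle (2.13), Pyy (2.67) and Gcg (1.60) were among the rises, and the export pump Abcc2 was among the falls (-1.76). Of the 14 lists called between the segments, the distal markers alone kept the call with an estimated correlation. On the same ileum arrays, smooth muscle markers stood 1.03 above control jejunum in the median, and the T cell list had a median of -0.85.

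Markers of several cell types differed between the segments. 11 of 13 smooth muscle genes were higher in control ileum and none lower (12 and 0 adjusted over the list alone). The smooth muscle list had a median of 1.03 (adjusted p = 5.10e-07, or adjusted p = 0.401 with an estimated correlation). The gamma-actin Actg2 (1.61) and the tropomyosin Tpm2 (1.18, 2 of 4 probe sets) were among them. 4 of 6 Paneth cell products were higher in control ileum and none lower (the same adjusted over the list alone). The Paneth list had a median of 1.42 (adjusted p = 0.00112, or adjusted p = 0.188 with an estimated correlation). 8 of 13 goblet cell products were higher in control ileum and 1 lower (9 and 1 adjusted over the list alone). The goblet list had a median of 0.63 (adjusted p = 7.93e-05, or adjusted p = 0.188 with an estimated correlation). Mmp7, the matrilysin of Paneth cells (1.91), and Atoh1, the factor of secretory cells (1.22), rose in ileum. 7 of 13 general epithelial genes were higher in control ileum and none lower (the same adjusted over the list alone). The epithelial identity list had a median of 0.36 (adjusted p = 0.000693, or adjusted p = 0.223 with an estimated correlation). With no scaling between arrays, the median of the epithelial list turned to lower in ileum, where the median shift of all probe sets was -0.40. Relative to the other genes, camera still called this list higher there. 4 of 10 T cell markers were lower in control ileum and none higher (6 and 0 adjusted over the list alone). The T cells list had a median of -0.85 (adjusted p = 0.00447, or adjusted p = 0.569 with an estimated correlation). Itgae, the integrin of intraepithelial lymphocytes, was lower (-1.40), but the T cell list lost its call with no scaling between arrays (adjusted p = 0.0570). 4 of 11 B and plasma cell markers were lower in control ileum and none higher (5 and 0 adjusted over the list alone). The B and plasma cells list had a median of -0.65 (adjusted p = 0.0193, or adjusted p = 0.567 with an estimated correlation). That call was lost without control jejunum 1 (adjusted p = 0.0511) or with no scaling between arrays, arrays centred on their medians or the probe set of smallest p (adjusted p = 0.144, 0.0531 and 0.0570). Enteric neurons and glia (median 0.49, 5 of 13 higher and 1 lower), crypt stem (0.44, 4 of 13 higher) and myeloid cells (-0.42, 3 of 13 lower) were not called as lists (camera adjusted p = 0.0529 for each). They were called under 11, 8 and 9 of 21 settings. Hormone genes parted by segment, with Gip (-5.23), Ghrl, ghrelin (-3.50), and Cck (-2.58) lower and Nts (1.51) higher in ileum. So did transcription factors, with Onecut2 (-4.42), Creb3l3 (-2.62) and Pdx1 (-2.33, 1 of 2 probe sets) lower and Osr2 (2.87) higher. Neither of those lists was called (adjusted p = 0.799 and 0.622), and in both the median lay above 0 while the mean and the test pointed down.

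Mutant and regional changes were then set side by side, both against the same 3 control jejunum arrays. Of 811 jejunum-enriched probe sets (525 genes; at least 2-fold lower in ileum), 317 (39.1%) fell in the mutant and none rose, where independent lists give 14.7 and simulated unchanged mutants 0.04. They included Lct, Cyp2b10, Reg1, Dnase1, Slc46a1 and Cd36. Of 700 ileum-enriched probe sets (506 genes), 270 (38.6%) rose, where independent lists give 12.2 and simulated unchanged mutants 0.04, and 1 fell. The shares were 11.7% and 51.4% with no scaling between arrays, and with arrays centred on their medians they were 26.9% and 42.2%, so their near equality rests on the scaling. The rises included Fabp6, Slc10a2, Mgat4c, Suox and Slc34a2. Not all regional genes moved alike: Slc2a2 (-1.08), Saa1 (2.49, adjusted p = 0.0701), Ada, adenosine deaminase (-0.46), Onecut2 and Ghrl (-0.03) were regional and not called in the mutant. Saa1 was called without mutant jejunum 1 (adjusted p = 0.0118) or control ileum 3 (adjusted p = 0.0418) or with no scaling between arrays, a pseudocount of 1 or array weights (adjusted p = 0.0468, 0.0118 and 0.0348), and Slc2a2 with a fit of the 2 groups alone (adjusted p = 0.0395). On a scale where control jejunum is 0 and control ileum 1, the median jejunum-enriched probe set stood at 0.549 ± 0.131 in the mutant (SD, n = 3; 0.410, 0.567 and 0.670 on mutant jejunum 1, 2 and 3). The median ileum-enriched one stood at 0.548 ± 0.0565 (0.515, 0.613 and 0.516). Simulated unchanged mutants gave 0.0424 and 0.0446. With no scaling between arrays these positions were 0.333 and 0.773, and no unchanged mutants were simulated for that setting. Counting all calls, 436 probe sets were up and 475 down in both comparisons and 3 were opposite, where independent lists give 42.7, 41.9 and 84.7 and the simulation 0.06, 0.04 and 0.05. Across probe sets, which are not independent replicates, the log2 fold changes correlated with r = 0.769 (simulated 0.174), and their covariance was 0.176 (simulated 0.0228, a difference of 0.154). The 3 control arrays cannot form 2 groups of 2, so part of the correlation, and part of the excess of shared calls over independent lists, may come from the shared controls. Simulated unchanged mutants carry no mutant effect, so almost no calls could arise in them. Their counts therefore do not show how many shared calls come from the shared controls. The simulated noise was also drawn for each probe set alone, without shifts that many probe sets of an array share. The simulated positions, r and covariance therefore do not bound what such shifts could give. For the positions, setting 1 control array against the mutant and the other two against ileum gave medians of 0.382 to 0.537. Control ileum did not stand at 1 on each of these scales. It stood at 0.859 and 0.875 with control jejunum 1 set against the mutant, where the mutant stood at 0.382 and 0.404. With control jejunum 2 or 3 it stood at 0.969 to 1.01. Without control jejunum 2 the jejunum-enriched falls numbered 161 and the ileum-enriched rises 154, without control jejunum 3 they were 161 and 166, and without mutant jejunum 2 they were 170 and 154. Without the same arrays, the shared calls numbered 196 up and 189 down, 191 and 183, and 191 and 206.

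**Figure D3:**
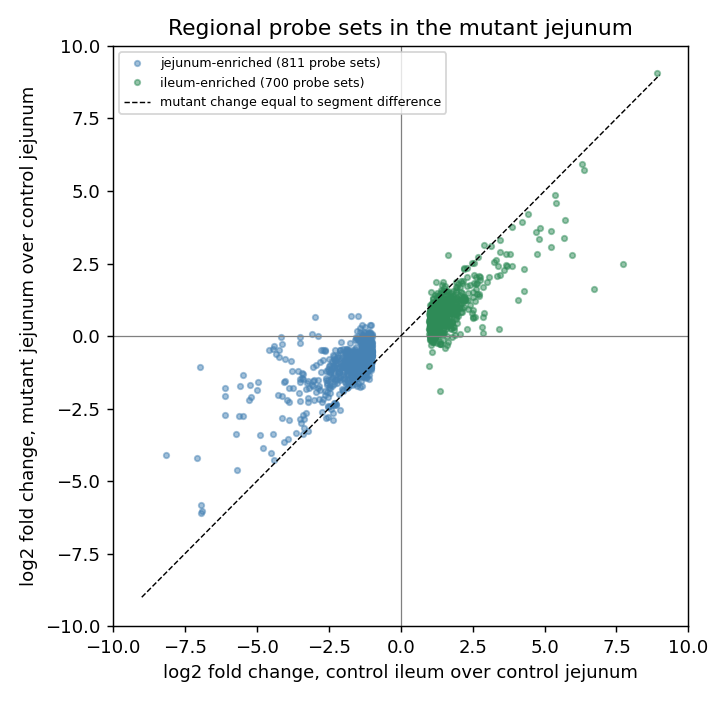
Log2 fold change of mutant over control jejunum against that of control ileum over control jejunum for 811 jejunum-enriched and 700 ileum-enriched probe sets; the dashed line marks equal changes. Of the jejunum-enriched probe sets, 784 (96.7%) lie below 0 in the mutant, and 668 (95.4%) of the ileum-enriched ones lie above 0, most of them short of the dashed line.

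The comparison of mutant jejunum with control ileum shows what still separated them. Slc2a2 (5.88) and Leap2 (4.32) were the genes furthest above ileum, and Fabp1 (4.15), Gata4 (4.12), Lct (4.05), Onecut2 (3.99), Ugt2a3 (3.88), the vesicle traffic gene Rab30 (3.83, 1 of 2 probe sets), the sugar transporter family member Slc5a4b (3.70) and Gip (3.54) followed. This order depends on the pseudocount, since several of these genes are near background in ileum: with 1 and 64, Onecut2 gave 6.59 and 2.38, and Leap2 4.97 and 3.30. Slc2a2 stood at 11.12 ± 0.52 in mutant jejunum and 5.24 ± 1.19 in control ileum (adjusted p = 0.000124). Saa1 was furthest below ileum, at 6.67 ± 1.50 against 11.90 ± 1.13 (-5.23, adjusted p = 0.00319), followed by Rpgrip1 (-3.46), and the ribonuclease gene Ang (-3.26, 2 of 3 probe sets). Next came ccdc198 (-3.19), Slc6a14 (-3.17, 1 of 2 probe sets), Bex1 (-2.86), the homeobox gene Hoxc8 (-2.76), Saa2 (-2.49), Bex4 (-2.21) and the fucosyltransferase Fut2 (-2.07). Hoxc8 likewise gave -4.77 and -1.44, and Rpgrip1 -4.16 and -2.42. Single arrays or the fit decided some of these calls. Fabp1 was lost without mutant jejunum 1 (adjusted p = 0.0726) or control ileum 2 (adjusted p = 0.0580) or with a fit of the 2 groups alone (adjusted p = 0.0571) and Slc6a14 without mutant jejunum 1 or 2 (adjusted p = 0.0962 and 0.0647) or control ileum 2 or 3 (adjusted p = 0.107 and 0.0679) or with a fit of the 2 groups alone (adjusted p = 0.0717). Saa2 was lost without mutant jejunum 1 or 2 (adjusted p = 0.0837 and 0.0635) or with a pseudocount of 64 or a fit of the 2 groups alone (adjusted p = 0.0509 and 0.0664) and Fut2 without mutant jejunum 1 or 2 (adjusted p = 0.0843 and 0.0615) or with a fit of the 2 groups alone (adjusted p = 0.0583). In total, 406 probe sets were higher and 372 lower in mutant jejunum than in control ileum (198 and 148 at least 2-fold, 326 and 288 genes). The groups did not overlap for 6035 (20.6%), where chance gives 10%. The counts were 123 and 76 without mutant jejunum 1, 204 and 226 without mutant jejunum 2, 251 and 160 without control ileum 1, 131 and 71 without control ileum 2, and 236 were higher without control ileum 3. The share higher in the mutant was 52.2%, but 98.3% with no scaling between arrays (8349 higher, 148 lower, median shift 0.41) and 79.1% with arrays centred on their medians (936 higher, 248 lower, median shift 0.10). This split thus rests on the scaling of the dimmer ileum arrays.

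Fat absorption, xenobiotic metabolism and fatty acid oxidation stayed above the ileal level in the mutant. 9 of 20 fat absorption genes were higher in mutant jejunum and none lower (14 and 0 adjusted over the list alone). The fat absorption list had a median of 0.52 (adjusted p = 2.03e-13, or adjusted p = 0.183 with an estimated correlation). 8 of 24 xenobiotic genes were higher in mutant jejunum and none lower (17 and 0 adjusted over the list alone). The xenobiotic metabolism list had a median of 1.14 (adjusted p = 9.83e-12, or adjusted p = 0.202 with an estimated correlation). 8 of 18 fatty acid oxidation genes were higher in mutant jejunum and none lower (13 and 0 adjusted over the list alone). The fatty acid oxidation list had a median of 0.59 (adjusted p = 7.30e-11, or adjusted p = 0.157 with an estimated correlation). Nutrient transport was not called as a list (median 0.07, adjusted p = 0.210; 2 of 16 genes higher and none lower, 2 and 1 adjusted over the list alone), but was called without mutant jejunum 3 (adjusted p = 0.0444) or control ileum 1 (adjusted p = 0.0234). Nor were the brush border hydrolases (median 0.19, adjusted p = 0.0503; 4 of 18 higher and 1 lower, 7 and 3 adjusted over the list alone), although they were called without mutant jejunum 3 (adjusted p = 0.00556) or control ileum 1 or 2 (adjusted p = 0.00311 and 0.0223) or with arrays centred on their medians, a pseudocount of 1, no filter, no intensity trend, array weights or the probe set of smallest p (adjusted p = 0.0455, 0.0351, 0.0373, 0.0430, 0.0248 and 0.0326). With an estimated correlation their adjusted p was 0.611 and 0.542. Examples from the called lists were Apoc2 (2.92) and Apoc3 (2.36), apolipoproteins of chylomicrons, the glutathione transferase Gstm3 (2.29), Nr1i3 (1.93) and Acaa2 (0.98). 4 of 8 purine breakdown genes were higher in mutant jejunum and none lower (4 and 1 adjusted over the list alone). The adenosine and purine catabolism list had a median of 0.70 (adjusted p = 0.0414, or adjusted p = 0.211 with an estimated correlation). This call was lost without control jejunum 1 (adjusted p = 0.0520), mutant jejunum 2 (adjusted p = 0.0838) or control ileum 3 (adjusted p = 0.0910) or with no scaling between arrays or no intensity trend (adjusted p = 0.0860 and 0.0618). Bile acid genes were not called as a list against ileum (median 0.14, adjusted p = 0.0528), although they were called without control jejunum 2 or 3 (adjusted p = 0.0443 and 0.0497), mutant jejunum 1 (adjusted p = 0.0259) or control ileum 1 (adjusted p = 0.0277) or with arrays centred on their medians, a pseudocount of 1, a pseudocount of 64 or no filter (adjusted p = 0.0437, 0.0468, 0.0492 and 0.0398), and Fgf15 (2.69) and Nr0b2 (2.56) were higher. 3 of 19 sterol synthesis genes were lower in mutant jejunum and none higher (11 and 0 adjusted over the list alone). The sterol synthesis list had a median of -0.52 (adjusted p = 6.59e-07, or adjusted p = 0.413 with an estimated correlation). With no scaling between arrays, the sterol synthesis median turned to higher in the mutant, where the median shift of all probe sets was 0.41. Relative to the other genes, camera still called this list lower there. The ghrelin gene Ghrl (3.47) was higher in the mutant than in ileum and Gcg (-1.90) lower. Of the 15 lists called in this comparison, 0 kept the call with an estimated correlation. On the same arrays, the smooth muscle list had a median of -1.15 and the T cell list a median of 1.07.

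Markers of several cell types also differed between mutant jejunum and control ileum. 10 of 13 smooth muscle genes were lower in mutant jejunum and none higher (13 and 0 adjusted over the list alone). The smooth muscle list had a median of -1.15 (adjusted p = 7.43e-14, or adjusted p = 0.202 with an estimated correlation). 6 of 13 enteric neuron and glia markers were lower in mutant jejunum and none higher (7 and 1 adjusted over the list alone). The enteric neurons and glia list had a median of -0.91 (adjusted p = 0.000571, or adjusted p = 0.202 with an estimated correlation). 4 of 6 Paneth cell products were lower in mutant jejunum and none higher (the same adjusted over the list alone). The Paneth list had a median of -1.39 (adjusted p = 7.58e-06, or adjusted p = 0.157 with an estimated correlation). Actg2 (-1.59), the neuronal gene Stmn2 (-1.18) and the Paneth ribonuclease Ang4 (-2.02, 1 of 2 probe sets) were lower. 2 of 13 goblet cell products were lower in mutant jejunum and none higher (6 and 0 adjusted over the list alone). The goblet list had a median of -0.37 (adjusted p = 0.000768, or adjusted p = 0.183 with an estimated correlation). The crypt stem list was lower with no member called (4 lower adjusted over the list alone). The crypt stem median was -0.33 (adjusted p = 0.000918, or adjusted p = 0.407 with an estimated correlation). The cell cycle list was lower with no member called, also adjusted over the list alone. Its median was -0.25 (adjusted p = 0.00896, or adjusted p = 0.542 with an estimated correlation), and its call was lost without mutant jejunum 1 or 2 (adjusted p = 0.183 and 0.0519) or control ileum 3 (adjusted p = 0.234). With no scaling between arrays, the medians of the goblet, crypt stem and cell cycle lists turned to higher in the mutant, where the median shift of all probe sets was 0.41. Relative to the other genes, camera still called these lists lower there. 4 of 10 T cell markers were higher in mutant jejunum and none lower (8 and 0 adjusted over the list alone). The T cells list had a median of 1.07 (adjusted p = 4.09e-08, or adjusted p = 0.253 with an estimated correlation). 1 of 13 myeloid markers was higher in mutant jejunum and none lower (6 and 0 adjusted over the list alone). The myeloid cells list had a median of 0.57 (adjusted p = 0.000810, or adjusted p = 0.516 with an estimated correlation). Itgae was higher in the mutant than in ileum (1.56). The B and plasma cell list was higher with no member called (6 higher adjusted over the list alone). The median was 0.52 (adjusted p = 0.0374, or adjusted p = 0.542 with an estimated correlation). It lost its call without mutant jejunum 3 (adjusted p = 0.108) or with no scaling between arrays, arrays centred on their medians, array weights or the probe set of smallest p (adjusted p = 0.411, 0.292, 0.0521 and 0.0652).

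A few genes in mutant jejunum lay outside the range of both control segments. Above both were 20 probe sets of 18 genes, and below both 14 of 13 genes. The comparisons with either segment share the 3 mutant arrays. Independent lists give 7.08 and 6.77 probe sets, values that leave this sharing out, so the excess over them may come from it, and no unchanged mutants were simulated for these counts. Genes are ranked here by their brightest probe set, and genes called in a dimmer one alone are counted but not ranked. Furthest above were S100g, the calcium binding protein of enterocytes, at 10.34 ± 1.36 in mutant jejunum against 7.54 ± 0.91 and 7.10 ± 0.42 in control jejunum and ileum, Fgf15 and Nr0b2, at 7.67 ± 0.31 against 5.35 ± 0.33 and 5.11 ± 0.15. Acta1, the skeletal alpha-actin (1.90 against control jejunum and 2.35 against control ileum), and Npl, an enzyme of sialic acid breakdown (1.51 and 2.20), came next. Furthest below was Rpgrip1, a ciliary protein gene, at 5.21 ± 0.11 against 8.51 ± 0.08 and 8.67 ± 0.11 (-3.30, adjusted p = 2.37e-07, and -3.46, adjusted p = 2.88e-07). Ang (-1.90 and -3.26), the glycogen phosphatase subunit Ppp1r3e (-1.08 and -1.42, 1 of 2 probe sets), Zcchc12 (-0.92 and -1.23) and the P450 gene Cyp2s1 (-0.89 and -1.18) followed. Ppp1r3e and Zcchc12 were near background in mutant jejunum (4.70 and 4.75). The size of such differences depends on the pseudocount, and their order may too. Ang, Rpgrip1 and Ppp1r3e, 3 of the 13 genes below both segments, lie on the chromosome that carries Gata4, as do 3.38% of the tested genes with a known chromosome. Some calls against control jejunum rest on single arrays or settings. S100g was lost without control jejunum 2 or 3 (adjusted p = 0.108 and 0.125) or mutant jejunum 1 or 2 (adjusted p = 0.0838 and 0.112) or with a fit of the 2 groups alone (adjusted p = 0.0596) and Acta1 without control jejunum 3 (adjusted p = 0.0511). Ppp1r3e was lost without control jejunum 2 or 3 (adjusted p = 0.0516 and 0.0744) or mutant jejunum 1 or 2 (adjusted p = 0.0635 and 0.0609) or with a fit of the 2 groups alone (adjusted p = 0.0518) and Zcchc12 without control jejunum 1, 2 or 3 (adjusted p = 0.0612, 0.144 and 0.0943), mutant jejunum 1 or 3 (adjusted p = 0.0965 and 0.0875) or control ileum 2 (adjusted p = 0.0586) or with no filter or a fit of the 2 groups alone (adjusted p = 0.0665 and 0.0784). Against control ileum, S100g was lost without mutant jejunum 1 or 2 (adjusted p = 0.0795 and 0.0637) or control ileum 1 or 2 (adjusted p = 0.0630 and 0.0628). Fgf15 was lost there without control jejunum 1, 2 or 3 (adjusted p = 0.0549, 0.0541 and 0.0572), mutant jejunum 1 (adjusted p = 0.0786) or control ileum 2 or 3 (adjusted p = 0.127 and 0.0899) or with no filter, no intensity trend or a fit of the 2 groups alone (adjusted p = 0.0588, 0.0523 and 0.0908) and Zcchc12 without mutant jejunum 1 (adjusted p = 0.0603) or control ileum 2 (adjusted p = 0.0595). The counts of 20 and 14 were 13 and 9 without control jejunum 1, 6 and 4 without control jejunum 2, and 5 and 3 without control jejunum 3. They were 6 and 6 without mutant jejunum 1, 8 and 6 without mutant jejunum 2, 11 and 9 without control ileum 1, 8 and 6 without control ileum 2, and 10 and 9 without control ileum 3.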

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

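Trimmed mean scaling was added after the data were seen, and the other settings were chosen before. As reported, 511 probe sets rose and 533 fell in the mutant, 2449 were higher and 2303 lower in control ileum, 406 higher and 372 lower in the mutant than in ileum, 436 up and 475 down in both mutant and ileum, 317 jejunum-enriched fell, 270 ileum-enriched rose, and 20 lay above and 14 below both segments. The values below are those that moved by over 1.5 times, or by more than the SD for a position, in the same order. With no scaling between arrays, 329 rose and 330 fell, 619 were higher and 10013 lower in ileum, and 8349 higher and 148 lower in the mutant than in ileum. The shared rises were 215, the ileum-enriched rises 133, the positions 0.333 and 0.773, and 103 lay above and 8 below both. With arrays centred on their medians, 320 fell, 1543 were higher in ileum, 936 higher in the mutant than in ileum, 290 down in both, the ileum-enriched position was 0.630 and 37 lay above both. With trimmed mean scaling no such value moved that far. With array weights, 1035 rose and 963 fell, 855 were higher and 825 lower in the mutant than in ileum, 835 up and 803 down in both, and 49 above and 41 below both segments. With a pseudocount of 64, 172 ileum-enriched rose and 9 lay below both. With no filter, 267 were higher in the mutant than in ileum and 7 lay below both. With no intensity trend, 247 were higher in the mutant than in ileum and 12 lay above both. With only the 2 groups compared in the fit, 162 were higher and 170 lower in the mutant than in ileum. With one probe set per gene, for fewer units tested, 1327 were higher and 1337 lower in ileum, 203 jejunum-enriched fell and 159 ileum-enriched rose. At adjusted p under 0.01, 169 rose and 169 fell, 1026 were higher and 1060 lower in ileum, and 87 higher and 53 lower in the mutant than in ileum. Regional genes of at least 4-fold gave 128 falls and 75 rises, and with no fold minimum 436 ileum-enriched rose. With an estimated correlation, the called lists went from 12, 14 and 15 to 2, 1 and 0. Leaving out single arrays gave 207 to 499 rises and 193 to 508 falls in the mutant, 1486 to 3106 higher and 1376 to 2848 lower in ileum, 123 to 549 higher and 71 to 500 lower in the mutant than in ileum. It gave 191 to 413 up and 183 to 465 down in both, 161 to 345 jejunum-enriched falls, 154 to 284 ileum-enriched rises, positions of 0.486 to 0.622 and 0.514 to 0.597, 5 to 28 above and 3 to 16 below both, and 10 to 14, 13 to 17 and 14 to 19 called lists. Beyond fewer arrays, fewer units or a stricter threshold, the cause was not tested. Replicate numbers link the groups by number alone: deviations from the group means of arrays with the same number correlated at -0.0727 to 0.165, and not every array correlated best with its own number. With the replicate block, 462 rose and 479 fell, 2375 were higher and 2210 lower in ileum, and 353 higher and 324 lower in the mutant than in ileum, and calls were gained by Saa1 in the mutant (adjusted p = 0.0283) and the brush border hydrolases between mutant and ileum (adjusted p = 0.0335). Of 149 calls of named genes, 130 kept their call under each of the 20 settings that tested them, 19 were lost under 1 or more, and 0 changed direction. Hoxc8 was tested under 17, since without control ileum 1, 2 or 3 it did not pass the filter. Signal over background limits the size of changes from dim levels: the Saa1 difference between mutant and control jejunum, from a control level of 4.18, was 2.49 as reported and 4.68 with a pseudocount of 1.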

Other observations

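The tests of strain DNA beside the null allele and of sequence differences under single probe sets were chosen before their results were seen. The interval and the window of genes used below for strain DNA were not part of the prediction written then. The tests of array brightness, shared control arrays, muscle share, harvest time, receptor activity and other splits were chosen only after the results they bear on were seen.

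Of the remaining lists tested between mutant and control jejunum with camera, 3 were called and shifted up without a single called member, also adjusted over the list alone. Tuft cell markers had a median of 0.67 over 7 genes (adjusted p = 0.0154, or adjusted p = 0.646 with an estimated correlation), a call that was lost without control jejunum 3 (adjusted p = 0.0614) or mutant jejunum 1 or 2 (adjusted p = 0.171 and 0.0641) or with a filter at the 60th percentile (adjusted p = 0.0621). The mean of this list stood at 1.22, 1.02 and -0.06 on mutant jejunum 1, 2 and 3, against 0.04, 0.21 and -0.25 on the control jejunum arrays, so mutant jejunum 3 showed no such shift. Rgs13, a regulator of G protein signalling in tuft cells, stood 1.36 above control (adjusted p = 0.239) and was called without mutant jejunum 3 (adjusted p = 0.0379) or with array weights (adjusted p = 0.0243). Antigen presentation had a median of 0.65 over 8 genes (adjusted p = 0.00868, or adjusted p = 0.646 with an estimated correlation), lost without control jejunum 2 (adjusted p = 0.0621) or mutant jejunum 1 (adjusted p = 0.0528). Its class II gene H2-Eb1 stood 1.47 above control (adjusted p = 0.252) and was called without control ileum 1 (adjusted p = 0.0494). Against control ileum the antigen presentation list was also higher in the mutant (median 0.62, adjusted p = 0.0284, or adjusted p = 0.542 with an estimated correlation), lost without mutant jejunum 1 (adjusted p = 0.0778) or control ileum 1 (adjusted p = 0.227) or with no scaling between arrays or array weights (adjusted p = 0.175 and 0.0911). Genes of stress and handling had a median of 0.36 over 15 genes (adjusted p = 0.0198, or adjusted p = 0.466 with an estimated correlation), lost without mutant jejunum 2 (adjusted p = 0.0812), with the heat shock genes Hspa1a and Hspa1b 2.25 and 2.61 above control (adjusted p = 0.352 and 0.186).

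The lists of interferon response, epithelial defence and circadian genes were not called. The interferon response had a median of -0.18 over 15 genes (adjusted p = 0.728) and no called member, also adjusted over the list alone. Epithelial defence had a median of 0.23 over 16 genes (adjusted p = 0.558). 1 of these genes fell, Reg1 (-4.62), and none rose (5 rose and 2 fell adjusted over the list alone). Circadian genes had a median of -0.09 over 14 genes (adjusted p = 0.127; called without control ileum 3 (adjusted p = 0.0444)), and 1 of them fell, the same count as adjusted over the list alone. It was Dbp, a clock output factor (-1.33, adjusted p = 0.0217), whose call was lost without control jejunum 2 or 3 (adjusted p = 0.0680 and 0.102) or mutant jejunum 2 or 3 (adjusted p = 0.0712 and 0.0623). Between control ileum and control jejunum 1 circadian gene was also called lower, and the largest change there was again that of Dbp (-1.11). Whether harvest time contributed to changes shared by mutant jejunum and control ileum was not tested. Of the 1044 probe sets called in the mutant, 911 (87.3%) were called in the same direction between the segments, and 130 (12.5%; 74 rose and 56 fell) were not called between them.

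At regional genes, mutant jejunum lay between control jejunum (0) and control ileum (1), with median positions of 0.549 and 0.548 in the jejunum-enriched and ileum-enriched classes. The tables argue against dimmer mutant arrays as the cause, since their mean log2 trimmed intensity lay at -0.0741 on that scale. The ileum arrays that set the end at 1 were dimmer, and the positions moved with no scaling between arrays, as given above. Shared control arrays are argued against as the whole cause, since with separate control arrays the position was 0.382 to 0.537. Control ileum stood at 0.859 to 1.01 on those scales. A larger share of muscle is argued against too, as the 11 smooth muscle genes called between the segments had a median position of -0.148. None of them rose or fell in the mutant. A candidate explanation is a partial change of the mutant jejunum toward the ileal pattern that goes with the mutant Gata4 genotype, a hypothesis found and tested on the same arrays. Of the 811 jejunum-enriched probe sets, 216 (26.6%) were called short of control ileum and 346 were called against neither segment. For the 700 ileum-enriched ones these counts were 194 (27.7%) and 289. Regional probe sets were chosen for a large difference on the same ileum arrays, which may make the positions smaller. The design text gives the same distance from the pylorus for control and mutant jejunum. An actual site further along the gut in the mutants stays open, as no segment between the sites was measured. Gata4 (9.50 in mutant jejunum, 5.38 in control ileum) and Slc2a2 (11.12 and 5.24) stood near control jejunum, while Fabp6, Slc10a2 and Cyp2b10 stood near control ileum. Gata4 is the targeted gene, and both it and Slc2a2 were picked as furthest above ileum on these arrays, so they do not decide the question.

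Rpgrip1, Ang and Ppp1r3e, 3 of the 13 genes below both control segments, lie on the chromosome of Gata4 with 3.38% of the 13805 tested genes that the gene table places on a chromosome (Fisher exact p = 0.00854, adjusted p = 0.0512 over 6 gene sets, which misses the threshold of 0.05). Strain DNA flanking the Gata4 null allele may lower them and cannot be told apart from an effect of the Gata4 genotype itself, because every mutant and no control carries that allele. Of 84 other genes with mutant calls outside the regional change, 2 lay on that chromosome, 0.704 times that share of 3.38% (2 of the 34 that fell, 1.74 times, Fisher exact p = 0.320, and 0 of the 50 that rose). This ratio met the bound set beforehand for arguing against strain DNA. Its 95% interval of 0.0856 to 2.46, which that prediction did not include, is too wide to decide. Of 668 genes with mutant calls that were also called between the segments, 24 lay on that chromosome, Ang and Slc7a8 among them. This was 1.06 times the share of 3.38% (Fisher exact p = 0.742). The densest window of 51 tested genes there gave a permutation p of 0.490 for a count as high anywhere in the genome. That window holds Ngdn and the 3 genes of the pattern itself and so decides nothing. A sequence difference under single probe sets may also lower these signals and cannot be told apart, as 1 of the 3 genes had 2 or more probe sets that fell (Ang, 2 of 3), while Rpgrip1 has 1 and Ppp1r3e fell in 1 of 2. Ppp1r3e, Rpgrip1 and Ang lie 90, 116 and 125 tested genes from Gata4, and the call of Ppp1r3e against control jejunum was lost without control jejunum 2 or 3 (adjusted p = 0.0516 and 0.0744) or mutant jejunum 1 or 2 (adjusted p = 0.0635 and 0.0609) or with a fit of the 2 groups alone (adjusted p = 0.0518).

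Fgf15 and Nr0b2 stood above both control segments in the mutant, by 2.69 and 2.56 against control ileum, and the Fgf15 call against ileum was lost without control jejunum 1, 2 or 3 (adjusted p = 0.0549, 0.0541 and 0.0572), mutant jejunum 1 (adjusted p = 0.0786) or control ileum 2 or 3 (adjusted p = 0.127 and 0.0899) or with no filter, no intensity trend or a fit of the 2 groups alone (adjusted p = 0.0588, 0.0523 and 0.0908). Nr0b2 was dim in control jejunum and control ileum (5.35 and 5.11), so the size of its difference depends on the pseudocount. A difference in harvest time may account for the levels of both genes and cannot be told apart. No circadian gene was called against control ileum, but the largest change there, that of Cry2 (-0.55, a size of 0.552), exceeds the bound of 0.3 that would argue against harvest time. The largest of 14 changes may pass that bound by noise alone, so this test could hardly have argued against harvest time. Higher activity of the bile acid receptor than in ileum may do so too, which its other targets leave open, as Slc51a, Slc51b and Fabp6 had log2 differences of 0.11, 0.13 and 0.16 (median 0.125; adjusted p = 0.711, 0.777 and 0.521), but Fabp6 was at the top of the normalized scale on every mutant array and could not have shown a larger one. With no scaling between arrays all 3 were called higher in the mutant (0.66, 0.74 and 0.55; adjusted p = 0.0173, 0.0162 and 0.0273), where the median shift of all probe sets was 0.41, and an effect of the Gata4 genotype by another route was not tested.

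Each comparison sets 3 arrays against 3, which makes 10 splits, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many calls. The calls numbered 1044 between mutant and control jejunum (highest other split 1), 4752 between the control segments (highest other 0) and 778 between mutant jejunum and control ileum (highest other 8).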
